A study of Mus musculus with 12 samples.

How the data were processed

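RNA of Hepa 1-6 cells, a mouse hepatoma line, was sequenced by the authors in 12 libraries, 3 in each of 4 groups. Per the labels, 400000 cells were plated on 6 cm dishes, transfected with 100 nM siRNA and again after 48 h (200 nM in total), and harvested at 96 h. The groups received a scrambled control pool (siC), a pool against Esrra (siERRa), a pool against Hcfc1 (siHCFC1) or both (siERRa+siHCFC1, the combined knockdown); how the dose was divided between the pools in the last is not stated. Total RNA was treated with DNase and made into libraries with a kit that does not mark the strand, so reads of overlapping antisense genes cannot be told apart; how messenger RNA was enriched is not stated. The authors' notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the mm10 mouse genome.

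The authors' deposited tables, 1 for each of 5 pairwise comparisons, hold read counts per gene and library as whole numbers, and a further deposited table holds TPM values (transcript abundance scaled to gene length and library size) of the 12 libraries. The same deposited comparison tables give the authors' log2 fold changes, p-values and adjusted p-values. The 5 count tables were merged: 377781 cells shared between tables differed in 0 cases, and 5451 blank cells were set to 0, since a gene that a table leaves out had at most 1 read over that table's libraries. Normalized and FPKM columns, 60 in number, were not used here. Of the TPM columns 4, 1 per group, carry the number 4 in place of 3. Over 10144 genes each of them had its highest correlation, of gene-centred log2 values, with library 3 of its group (lowest r = 1 after rounding, next highest 0.652), so they were taken as these libraries, and TPM is given by group. Total counts per library ran from 21.4 to 33.2 M, which gives the mitochondrially encoded share of a library 95% Wilson intervals at most 0.0288 points wide for counting error only. Within each group, no 2 libraries were copies of each other (lowest chi-square per degree of freedom 40.3).

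Every choice of test, filter, gene list and named-gene rule was fixed before the data were examined, except the settings said to be chosen afterwards. The fixed design set limma on log2(TPM + 0.5), with edgeR in its place if whole-number counts of all 12 libraries were present; they were, so edgeR was used. Of 24326 genes, 15965 passed filterByExpr and were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, estimateDisp, glmQLFit, glmQLFTest) in a model of 4 group means with 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have passed the threshold. Comparisons were each knockdown against siC, the combined knockdown against each single one, the departure of the combined log2 change from the sum of the single ones, and a test over all 3 comparisons with siC. Standard errors of log2 changes come from the edgeR fit, and CPM values are TMM-scaled.

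Gene lists, 35 in number, were written from general knowledge; 33 with at least 3 measured members were tested with camera (limma 3.58.1, inter-gene correlation 0.01, adjusted over lists within a comparison), and again with the correlation estimated for each list. The 2 untested lists were the siRNA targets and the ERR and HCFC family members, with 2 measured genes each. Members are counted when called over all genes and when adjusted over the list alone. Genes named in the report follow a rule: Esrra and Hcfc1; per comparison the 6 largest rises and 6 largest falls among genes past the threshold with group ranges that do not overlap, a mean TPM of at least 5 in the higher group and no predicted name; up to 3 called members with the smallest adjusted p of each list described; 5 per direction for the departure and 6 for genes changed further by the combination. This gave 114 genes in 175 gene-comparison pairs. Of these genes, 3 are not reported here. For a group with 0 counts a bound of 3 counts over the group was used in place of 0. Of the 114, 18 are uncertain because more than 20% of their 31-base words recur in other genes or more than 20% of their exon bases overlap another gene, and each one reported is marked with its share. Gene positions are those of the deposited tables, and 108 of 114 equal those of the annotation.

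The test was run on simulated data with 200 changed genes. For siERRa against siC it recovered 0 of 67 genes changed 1.5-fold, 11 of 67 (16.4%) changed 2-fold and 38 of 66 (57.6%) changed 4-fold, with 1 false call. For siHCFC1 against siC the numbers were 2 of 67, 9 of 67 (13.4%) and 46 of 66 (69.7%), with 2 false calls, and for the departure 0, 2 and 31, with 3 false calls. A list shifted 1.25-fold was called and 0 of 32 others were. Genes were drawn independently there, without correlation between list members. The list result thus does not show how often real lists are falsely called. Data simulated with no effect gave the correlation that shared siC libraries produce alone when all libraries are independent. In both simulations each library was drawn independently with the dispersions of the main fit. Variation shared by libraries of a number was not simulated, so these values may not hold for the real libraries.

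Alternatives were a stricter adjusted p of 0.01, a fold of at least 1.5, no filter, TPM of at least 5, RLE scaling, a robust fit, the model without mitochondrially encoded genes, limma on log2 TPM with pseudocounts of 0.5, 0.1 and 2, quantile normalization and library weights, a block for the library number, DESeq2 1.42.0, and each library left out in turn; limma settings change the test along with the scale. Added after seeing the data were fits without the libraries numbered 2 or 3 and fits of the compared libraries only. A count of ERR and THAP11/ZNF143 promoter motifs, with its alternatives, needs genome sequence and was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.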

Results

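Mouse hepatoma cells (Hepa 1-6) received a pool of small interfering RNAs (siRNAs) against Esrra, the gene of the orphan nuclear receptor ERRα, a pool against Hcfc1, the gene of the chromatin-associated coregulator HCFC1, both pools, or a scrambled control. RNA was sequenced 96 h after the first transfection, and each of the 4 groups (siC, siERRa, siHCFC1 and the combined knockdown, siERRa+siHCFC1) held 3 libraries. The libraries held 21.4 to 33.2 M counts in genes. Group means were 24.8 ± 3.08, 27.0 ± 5.41, 25.8 ± 4.01 and 25.9 ± 2.82 M in that order (SD, n = 3 each). Genes encoded on the mitochondrial chromosome took 4.49% ± 2.08 of the counts in siC, 6.19% ± 3.66 in siERRa, 6.75% ± 3.55 in siHCFC1 and 8.19% ± 5.66 in the combined knockdown (SD, n = 3 each). Single libraries ran from 2.37% to 14.5%, with 95% Wilson intervals, which cover counting error only, at most 0.0288 points wide. The labels leave open whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical. The main fit has no term for the library number, so variation shared by libraries of a number counts as spread. With a block for that number, 1625, 3974 and 4067 genes passed the threshold against siC after siERRa, siHCFC1 and both. Without it 70, 1066 and 1100 did.

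Esrra RNA fell in both groups that received its siRNA. It averaged 47.0 ± 4.72 CPM (counts scaled to library size) in siC, 12 ± 4.34 in siERRa, 56.7 ± 9.26 in siHCFC1 and 17.3 ± 4.21 in the combined knockdown (SD, n = 3 each). This was a 3.92-fold fall in siERRa (log2 -1.97, SE 0.265, adjusted p = 0.00702) and a 2.72-fold fall in the combined knockdown (log2 -1.44, SE 0.26, adjusted p = 0.00478), at chr 19, 6910977 to 6921813 of mm10. Hcfc1 (chr X, 73942792 to 73966357) averaged 173 ± 28.2 CPM in siC, 146 ± 36.7 in siERRa, 96.2 ± 29.9 in siHCFC1 and 113 ± 22 in the combined knockdown (SD, n = 3 each). Its 1.80-fold difference between siHCFC1 and siC missed the threshold (log2 -0.85, SE 0.26, adjusted p = 0.0668), as did that of the combined knockdown against siC (log2 -0.61, SE 0.259, adjusted p = 0.182). Every siHCFC1 library (66.2 to 126 CPM) lay below every siC library (142 to 198 CPM). Neither siRNA moved the other's target past the threshold: Hcfc1 after siERRa differed by -0.25 on the log2 scale (adjusted p = 0.871) and Esrra after siHCFC1 by 0.27 (adjusted p = 0.619). Between the combined knockdown and its single knockdowns the 2 genes also stayed short of it, with Esrra 0.53 against siERRa and -1.71 against siHCFC1 (adjusted p = 0.0866), and Hcfc1 -0.36 against siERRa and 0.23 against siHCFC1. With the libraries numbered 3 left out of all groups, a setting chosen after seeing the data, the Esrra differences from siC were -1.79 (adjusted p = 0.17) and -1.16 (adjusted p = 0.1). Over 23 settings the adjusted p of Esrra ran from 3.96e-11 to 0.17 in siERRa and from 9.99e-07 to 0.1 in the combined knockdown, and that of Hcfc1 in siHCFC1 from 0.000613 to 0.299. For the combined knockdown that of Esrra ran from 3.1e-08 to 0.722 against siHCFC1 and from 0.00162 to 0.636 against siERRa. That of Hcfc1 against siERRa ran from 0.0185 to 0.888, so some settings called these differences.

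**Figure D1:**
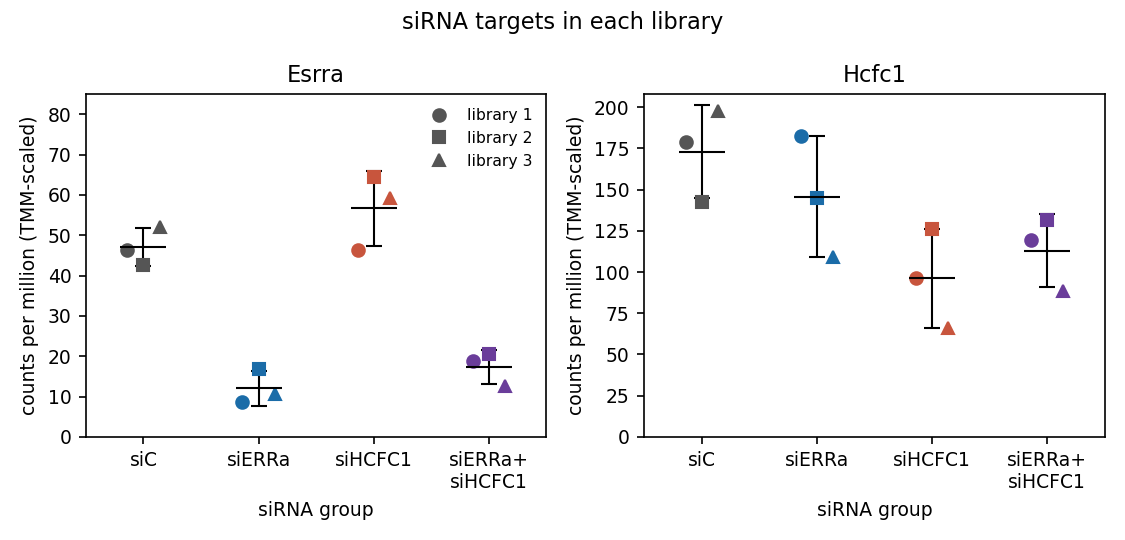
Esrra and Hcfc1 in each of the 12 libraries, in TMM-scaled CPM, by siRNA group. Bars give the mean and SD of 3 libraries.

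After knockdown of Esrra alone a small set of genes passed the threshold in the main fit, among them Serpind1, Ppbp, Fgfbp1 and Gdf15. With a block for the library number 1625 passed it, so the small count does not show a small effect. Serpind1, which encodes the thrombin inhibitor heparin cofactor II (chr 16, 17331371 to 17343575), rose 19.7-fold, from 0.751 ± 0.277 to 14.2 ± 11.4 TPM (SD, n = 3 each). Without siERRa library 2 the fold of Serpind1 was 10.4 and its call ended, as it did without siC library 1, 2 or 3. The platelet chemokine Ppbp (chr 5, 90768518 to 90770063) rose from 160 ± 49.3 to 740 ± 295 TPM. Fgfbp1, a carrier of fibroblast growth factors (chr 5, 43978858 to 43981779), fell from 138 ± 36.3 to 27.0 ± 1.13 TPM, and the stress cytokine Gdf15 from 209 ± 39.7 to 61.8 ± 21.1 TPM (SD, n = 3 each). In log2 terms the largest rises were Serpind1 4.30 (SE 0.734), the chemokine scavenger Ackr3 3.23 (SE 0.624) and Ppbp 2.26 (SE 0.319). The receptor Pilrb2 2.12 (SE 0.421), the trefoil factor Tff3 2.06 (SE 0.407) and Trim12c 1.90 (SE 0.25) came next, all 6 with an adjusted p of at most 0.0443. The largest falls were Rpl30-ps10 -2.68 (SE 0.315), the annexin Anxa8 -2.52 (SE 0.378) and Fgfbp1 -2.31 (SE 0.265). The matrix protein Adamtsl4 -2.21 (SE 0.301), the phosphatase Ppm1j -2.09 (SE 0.282) and Esrra itself came next, all 6 with an adjusted p of at most 0.0126. The glycogen-targeting subunit Ppp1r3c rose (0.98, SE 0.169, adjusted p = 0.0255). Gdf15 fell (-1.70, SE 0.305, adjusted p = 0.0301), as did the replication helicase subunit Mcm6 (-1.26, SE 0.223, adjusted p = 0.0277). The cytokinesis motor Kif23 (-0.82, SE 0.161, adjusted p = 0.044) and the centromeric histone Cenpa (-0.96, SE 0.196, adjusted p = 0.0487) fell too. Of Pilrb2, Trim12c and the pseudogene Rpl30-ps10, 48.2%, 48.1% and 96.8% of the 31-base words recur in other genes, so their reads may come from those.

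In all, 70 of 15965 tested genes passed the threshold against siC, 22 higher and 48 lower (edgeR). The call ended in at least 1 leave-one-out fit for 11 of the 17 genes named above and held in all 6 for Esrra, Adamtsl4, Fgfbp1, Ppm1j, Rpl30-ps10 and Trim12c. Ackr3, Pilrb2, Mcm6, Kif23 and Cenpa lost it in all 6. Leaving out siC library 1, 2 or 3 left 9, 9 or 8 genes, and leaving out siERRa library 1, 2 or 3 left 17, 16 or 24. DESeq2 called 395, and the authors' deposited comparison calls 289, 119 higher and 170 lower, with all 70 among them in the same direction.

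By camera with an assumed correlation of 0.01, lists of cell division, stress and lipid synthesis were lower and complex I was higher after siERRa, and none of these calls held with an estimated correlation. Genes of mitosis had a median log2 change of -0.69, with 29 of 30 members below 0 (camera adjusted p = 1.69e-18). Of them 2 were called over all genes and 19 when adjusted over the list alone. The integrated stress response (-0.52, 18 of 20 below 0, adjusted p = 5.24e-08) had 1 called member, Gdf15, and 6 adjusted over the list alone. Cholesterol biosynthesis (-0.41, 21 of 24 below 0, adjusted p = 4.81e-06) had 0 called and 2 adjusted over the list alone. For these 3 lists adjusted p = 0.323 with an estimated correlation. Fatty acid synthesis (-0.35, adjusted p = 0.00326), p53 targets (-0.31, adjusted p = 0.000838), the NRF2 program (-0.29, adjusted p = 0.00123) and one-carbon metabolism (-0.25, adjusted p = 0.00133) were lower as well. They had 1, 3, 0 and 6 members adjusted over the list alone, and only Gdf15, a p53 target too, over all genes. Their values were adjusted p = 0.504, 0.526, 0.804 and 0.378 with an estimated correlation. Without siERRa library 2 the medians of the integrated stress response, p53 targets and one-carbon metabolism were -0.34, -0.12 and -0.16, and the call of NRF2 (-0.18) ended. Without siC library 3 those of p53 targets, NRF2 and one-carbon metabolism were -0.15, -0.17 and -0.16. Without siERRa library 3 that of NRF2 was -0.45 and the call of fatty acid synthesis (-0.20) ended.

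Complex I was higher after siERRa (median 0.27, 33 of 37 members above 0, adjusted p = 8.79e-05). So were the 7 measured histone genes (1.02, adjusted p = 0.00169) and the 13 mitochondrially encoded subunits (0.51, adjusted p = 0.0274). All 3 lists had 0 members called over all genes or adjusted over the list alone, and adjusted p = 0.804, 0.378 and 0.804 with an estimated correlation. The last list moves with the mitochondrial share of counts, 4.49% in siC and 6.19% in siERRa. Other lists of mitochondrial energy metabolism, the process ERRα is best known for, stayed short of the threshold with 0 members called. These were complexes II to IV (0.15, adjusted p = 0.157), ATP synthase (0.21, adjusted p = 0.0954) and the tricarboxylic acid (TCA) cycle (0.020, adjusted p = 0.875). Mitochondrial fatty acid oxidation (0.069, adjusted p = 0.29), mitochondrial ribosomal proteins (0.11, adjusted p = 0.167) and the ERR coactivators (-0.17, adjusted p = 0.167) were among them. Cytosolic ribosomal proteins (-0.12, adjusted p = 0.0506), S-phase genes (-0.14, Mcm6 called, adjusted p = 0.0532) and the unfolded protein response (-0.12, adjusted p = 0.29) stayed short too. Calls of these higher lists ended without siERRa library 3 for complex I (0.046) and histones (0.74), and without siERRa library 2 for the mitochondrially encoded genes (-0.096). They ended without siC library 2 for histones (0.75) and without siC library 3 for the mitochondrially encoded genes (0.13), whose median was 0.90 without siC library 2 and 0.89 without siERRa library 3.

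Knockdown of Hcfc1 alone moved far more genes past the threshold in the main fit, among them the endoplasmic reticulum chaperone Hspa5, the nuclear lamina gene Lmnb2 and the interferon-inducible GTPase Gbp2. Ttc41 (chr 10, 86705811 to 86776844), close to silent in siC, rose 41-fold from 1.06 ± 0.382 to 38.4 ± 7.22 TPM (SD, n = 3 each). Hspa5 (chr 2, 34771970 to 34777547) rose from 1151 ± 137 to 3073 ± 814 TPM. Lmnb2 (chr 10, 80901203 to 80918245) fell from 17.6 ± 1.91 to 0.850 ± 0.430 TPM, and Mettl26 (chr 17, 25875464 to 25886007) from 113 ± 20.5 to 9.89 ± 4.42 TPM. The complex I subunit Ndufa3 (chr 7, 3617373 to 3620327) fell from 75.6 ± 2.65 to 14.4 ± 4.42 TPM (SD, n = 3 each). The largest rises in log2 were Ttc41 5.36 (SE 0.41), the steroid-metabolizing Akr1c14 3.70 (SE 0.484) and Trim12c 3.63 (SE 0.263). Gbp2 3.53 (SE 0.485), Pisd-ps1 3.50 (SE 0.595) and the cathepsin Ctso 3.36 (SE 0.373) came next, all 6 with an adjusted p of at most 0.00339. The largest falls were Lmnb2 -4.17 (SE 0.571), the G protein subunit Gna15 -4.11 (SE 1.04) and Zfp383 -3.67 (SE 0.737). The deacetylase Hdac11 -3.38 (SE 0.562) and Mettl26 -3.37 (SE 0.334) were also among them, these 5 with an adjusted p of at most 0.0297. Leaving out siHCFC1 library 1 moved Gna15 to -6.34, leaving out siHCFC1 library 2 moved it to -3.52 and ended its call, and its call also ended without siHCFC1 library 3 or any 1 of the siC libraries. Without siHCFC1 library 2 Lmnb2 was at -4.78 and Pisd-ps1 at 2.84, and without siHCFC1 library 3 Zfp383 was at -3.03 and Hdac11 at -4.32. Of Trim12c and Pisd-ps1, 48.1% and 27.7% of the 31-base words recur in other genes.

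In all, 1066 of 15965 genes passed the threshold in siHCFC1 against siC, 393 higher and 673 lower (edgeR). With the TPM as deposited in place of the scaled counts (limma), 157 were higher and 684 lower, and the median shift per gene between the fits was -0.158 over 14443 genes. Leaving out siC library 1, 2 or 3 left 420, 562 or 445 genes, and leaving out siHCFC1 library 1 or 2 left 597 or 643. Of 54 named genes, 22 kept their call in all 6 leave-one-out fits, including every one named in the paragraph before except Gna15. Among those that lost it in all 6 were Acacb, Bmf, Dbp, Dld, Mcm5, Nr1d2, Pcx and Pfas. DESeq2 called 1865, and the authors' deposited comparison calls 1667, 773 higher and 894 lower, with 1023 of the 1066 in the same direction.

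Interferon-response genes rose after siHCFC1, with a median of 0.79 and 23 of 24 members above 0 (camera adjusted p = 6.13e-09, adjusted p = 0.0374 with an estimated correlation). Of them 8 were called higher and 0 lower, and 11 higher when adjusted over the list alone. Beside Gbp2 they included Gbp3 (3.28, SE 0.62, adjusted p = 0.00646, chr 3, 142560026 to 142573209) and the immunoproteasome subunit Psmb8 (1.12, SE 0.235, adjusted p = 0.012). Without siC library 3 Gbp3 was at 3.91. Over 22 settings its log2 change ran from 1.05 to 3.91, with the call lost in 1. All 17 members of the unfolded protein response lay above 0 (median 0.73, adjusted p = 7.11e-08, adjusted p = 0.612 with an estimated correlation), with 4 called and 9 adjusted over the list alone. Among them were Hspa5 1.59 (SE 0.281, adjusted p = 0.00414), Herpud1 0.85 (SE 0.198, adjusted p = 0.0198) and Creld2 1.28 (SE 0.319, adjusted p = 0.0286). Histone genes were higher (1.76, adjusted p = 0.00123, adjusted p = 0.465 with an estimated correlation), with 2 of 7 called and 3 adjusted over the list alone. The called ones were Hist1h1c 1.71 (SE 0.406, adjusted p = 0.0216) and Hist1h2bc 1.90 (SE 0.491, adjusted p = 0.0333), the latter with 33.5% of its words shared with other genes. The nuclear receptor and clock list was higher (0.17, adjusted p = 0.00775, adjusted p = 0.157 with an estimated correlation), with 4 called and 6 adjusted over the list alone. It held Nfil3 1.18 (SE 0.29, adjusted p = 0.0264), Nr1d2 0.54 (SE 0.146, adjusted p = 0.0426) and Dbp 0.84 (SE 0.231, adjusted p = 0.0438). The median of the clock list was 0.32 without siC library 2, 0.35 without siHCFC1 library 1 and 0.33 without siHCFC1 library 2, and its call ended without siHCFC1 library 3 (0.14).

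Higher after siHCFC1 with 0 members called over all genes or adjusted over the list alone were 3 lists. These were p53 targets (0.33, adjusted p = 0.00617), lysosome and autophagy genes (0.38, adjusted p = 0.0363) and mitochondrially encoded subunits (0.82, adjusted p = 0.0363). Their values were adjusted p = 0.622, 0.622 and 0.788 with an estimated correlation. The mitochondrial share of counts was 6.75% in siHCFC1 and 4.49% in siC. The antioxidant gene Nqo1 rose (1.29, SE 0.277, adjusted p = 0.0128) without its list (0.18, adjusted p = 0.0768). List calls of siHCFC1 ended without siHCFC1 library 3 for p53 targets (0.22) and the lysosome list (0.34). Those of the lysosome and mitochondrially encoded lists ended without siHCFC1 library 2 (0.18 and 0.16) and without siC library 3 (0.32 and 0.49).

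Lower after siHCFC1 were the cytosolic ribosomal proteins, with a median of -0.50 and 73 of 75 members below 0 (adjusted p = 6.13e-09, adjusted p = 0.788 with an estimated correlation). Of them 6 were called and 22 adjusted over the list alone, among them Rplp1 -1.03 (adjusted p = 0.0279), Rps21 -0.92 (SE 0.234, adjusted p = 0.0313) and Rps13 -1.08 (adjusted p = 0.0319). Rplp1 and Rps13 share 75.1% and 23.0% of their words with other genes, pseudogenes closest. S-phase genes were lower (-0.35, adjusted p = 0.000277, adjusted p = 0.612 with an estimated correlation), with 4 called and, adjusted over the list alone, 12 lower and 1 higher. They included the primase Prim1 -2.14 (SE 0.336, adjusted p = 0.00218), E2f1 -0.69 (SE 0.172, adjusted p = 0.0289) and Mcm5 -0.87 (SE 0.223, adjusted p = 0.0326). Complex I was lower too (-0.30, adjusted p = 0.00617, adjusted p = 0.788 with an estimated correlation), with 6 called and 8 adjusted over the list alone. Its called members included Ndufa3 -2.21 (SE 0.321, adjusted p = 0.00132), Ndufa10 -1.22 (SE 0.228, adjusted p = 0.00615) and Ndufv2 -1.05 (SE 0.241, adjusted p = 0.0186). This call ended without siHCFC1 library 2 (-0.25), and without it the median of the ribosomal proteins was -0.33.

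Single enzymes fell after siHCFC1 in lists that stayed short of the threshold. In complexes II to IV (-0.14, adjusted p = 0.115) these were Cox7b -0.79 (SE 0.187, adjusted p = 0.0212) and Uqcr10 -1.02 (SE 0.252, adjusted p = 0.0273). In the TCA cycle (-0.077, adjusted p = 0.235) they were Dlat -1.39 (SE 0.218), Dld -0.67 (SE 0.161) and Pcx -0.81 (SE 0.216), with an adjusted p of at most 0.0393. Mitochondrial ribosomal proteins split, 4 called higher and 8 lower (-0.17, adjusted p = 0.14). Mrpl24 -3.11 (SE 0.293, adjusted p = 8.01e-05) and Mrpl2 -1.47 (SE 0.253, adjusted p = 0.00357) fell and Mrps18b 1.31 (SE 0.178, adjusted p = 0.000838) rose. Mrpl24 and Mrps18b share 27.2% and 31.6% of their words with other genes, antisense neighbours closest. In purine synthesis Impdh2 (-1.58, SE 0.276, adjusted p = 0.00401) and Pfas (-0.91, adjusted p = 0.0469) fell (list -0.22, adjusted p = 0.162), Impdh2 with 43.7% of its words shared. The ERR coactivator Pprc1 fell (-1.08, SE 0.168, adjusted p = 0.00206), its list at 0.041 (adjusted p = 0.625). Among partner proteins of HCFC1 (0.0057, adjusted p = 0.673) Creb3 rose (1.03, SE 0.274, adjusted p = 0.0392) and E2f1 fell. Lists of ATP synthase (0.055, adjusted p = 0.625), fatty acid oxidation (-0.021, adjusted p = 0.809) and mitosis (-0.18, adjusted p = 0.265) stayed short of the threshold. So did cholesterol biosynthesis (-0.023, adjusted p = 0.544), fatty acid synthesis (-0.066, adjusted p = 0.214) and the integrated stress response (0.17, adjusted p = 0.264). Acacb, of fatty acid synthesis, fell (-1.01, SE 0.284, adjusted p = 0.0469).

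Among the genes that fell after the combined knockdown were several of sterol and fatty acid synthesis, and among those that rose were several histone and interferon-inducible genes. Lanosterol synthase Lss (chr 10, 76531588 to 76557138) fell from 18.8 ± 1.14 to 7.38 ± 1.52 TPM (SD, n = 3 each). Phosphomevalonate kinase Pmvk (chr 3, 89454541 to 89469013) fell from 58.0 ± 1.21 to 19.0 ± 8.58 TPM and the desaturase Fads2 (chr 19, 10064164 to 10101503) from 257 ± 38.8 to 91.9 ± 8.58 TPM. Gulo, the last enzyme of vitamin C synthesis (chr 14, 65986786 to 66009207), rose from 4.34 ± 1.96 to 60.7 ± 26.8 TPM (SD, n = 3 each). The largest rises against siC were Ttc41 5.30 (SE 0.409), Gbp4 4.05 (SE 0.616) and Gulo 3.99 (SE 0.617). Pisd-ps2 3.82 (SE 0.636), Gbp2 3.76 (SE 0.488) and Trim12c 3.68 (SE 0.263) came next, all 6 with an adjusted p of at most 0.00307. The largest falls were Fam219a -4.09 (SE 0.797), Lmnb2 -4.08 (SE 0.569) and the DNA glycosylase Neil1 -4.07 (SE 0.895). R3hdml -3.99 (SE 0.621), Fam234b -3.53 (SE 0.462) and Mettl26 -3.46 (SE 0.335) came next, all 6 with an adjusted p of at most 0.014. Without siC library 2 Gbp4 was at 4.64. Leaving out library 2 of the combined knockdown moved Lmnb2 to -4.71 and Neil1 to -5.56, leaving out library 3 moved Neil1 to -3.45 and Fam219a to -3.47, and leaving out library 1 ended the call of Neil1. Of Pisd-ps2, 38.5% of the 31-base words recur in other genes, as do 48.1% of Trim12c.

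In all, 1100 of 15965 genes passed the threshold, 452 higher and 648 lower (edgeR). With the TPM as deposited (limma) 240 were higher and 691 lower, and the median shift per gene was -0.134. Leaving out siC library 1, 2 or 3 left 476, 614 or 499 genes, and leaving out library 1, 2 or 3 of the combined knockdown left 684, 591 or 580. Of 58 named genes, 31 kept their call in all 6 leave-one-out fits, among them the 12 of the largest rises and falls except Neil1. Among those that lost it in all 6 were Bub1b, Cry1, Csf1r, E2f1, Ndufv2, Nr2f6, Prim1, Shmt2 and Zbtb17. DESeq2 called 1899, and the authors' deposited comparison calls 2154, 1044 higher and 1110 lower, with 1097 of the 1100 in the same direction.

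Cholesterol biosynthesis was lower in all 24 members after the combined knockdown (median -0.66, camera adjusted p = 2.38e-10, adjusted p = 0.0856 with an estimated correlation). Of them 7 were called and 15 adjusted over the list alone, led by Lss -1.23 (SE 0.178, adjusted p = 0.00135), Nsdhl -1.29 (SE 0.224, adjusted p = 0.00377) and Pmvk -1.52 (SE 0.273, adjusted p = 0.00455). Fatty acid synthesis went with it (-0.45, adjusted p = 0.000234, adjusted p = 0.309 with an estimated correlation), with 4 called and 5 adjusted over the list alone. These included Fads2 -1.36 (SE 0.211, adjusted p = 0.00198), Scd1 -1.10 (SE 0.227, adjusted p = 0.00991) and Acss2 -1.01 (SE 0.26, adjusted p = 0.0315). Cytosolic ribosomal proteins were lower (-0.50, 74 of 75 below 0, adjusted p = 1.18e-09, adjusted p = 0.952 with an estimated correlation), with 7 called and 18 adjusted over the list alone. Among them, Rplp1 -1.33 (adjusted p = 0.00693) and Rpl17 -1.04 (adjusted p = 0.0205) share 75.1% and 46.1% of their words with other genes. Mitosis was lower (-0.54, 28 of 30 below 0, adjusted p = 5.08e-06, adjusted p = 0.808 with an estimated correlation), with 2 called and 8 adjusted over the list alone. The called genes were Aurkb -0.66 (SE 0.177, adjusted p = 0.0365) and Bub1b -0.71 (SE 0.191, adjusted p = 0.0393). S-phase genes were lower (-0.30, adjusted p = 0.000324, adjusted p = 0.48 with an estimated correlation), with 3 called and 3 adjusted over the list alone. These were Mcm6 -1.33 (SE 0.223, adjusted p = 0.00316), E2f1 -0.64 (adjusted p = 0.0367) and Prim1 -1.21 (adjusted p = 0.0378).

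Histone genes were higher after the combined knockdown, all 7 above 0 (median 2.83, adjusted p = 5.05e-07, adjusted p = 0.0856 with an estimated correlation). Of them 4 were called and 6 adjusted over the list alone. They included Hist1h1d 4.76 (SE 0.974, adjusted p = 0.00939, chr 13, 23553262 to 23560686), Hist1h1c 2.12 (SE 0.411, adjusted p = 0.00692) and Hist1h2bc 2.12 (SE 0.494, adjusted p = 0.0194, 33.5% of words shared). Without siC library 3 Hist1h1d was at 7.36, and over 22 settings its log2 change ran from 1.16 to 7.36, so its size depends on the setting. Interferon-response genes were higher (0.90, 19 of 24 above 0, adjusted p = 2.93e-07, adjusted p = 0.0856 with an estimated correlation). Over all genes 8 were called higher and 1 lower, and adjusted over the list alone 13 higher and 2 lower. Beside Gbp2 they included Gbp3 3.43 (SE 0.623, adjusted p = 0.00494), at 4.05 without siC library 3, and Psmb8 1.37 (SE 0.236, adjusted p = 0.00368). Over 22 settings Gbp3 ran from 1.15 to 4.05, with the call lost in 1. The nuclear receptor and clock list was higher (0.32, adjusted p = 0.0083, adjusted p = 0.0856 with an estimated correlation). Over all genes 2 were called higher and 1 lower, and adjusted over the list alone 9 higher and 1 lower. Per2 1.45 (SE 0.35, adjusted p = 0.0232) and Nr2f6 0.66 (adjusted p = 0.0251, 54.4% of its exon bases under an antisense gene) rose and Cry1 -0.85 (SE 0.241, adjusted p = 0.0476) fell. The mitochondrially encoded subunits (0.95, 0 called or adjusted over the list alone, adjusted p = 0.0157, adjusted p = 0.952 with an estimated correlation) moved with a mitochondrial share of 8.19% against 4.49%. Their call ended without siC library 3 (0.67) or library 2 of the combined knockdown (0.067).

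Single members also changed in lists that stayed short of the threshold after the combined knockdown. Complex I (-0.036, adjusted p = 0.604) held falls of Ndufa3 -1.82 (SE 0.315, adjusted p = 0.00377), Ndufa10 -0.81 (adjusted p = 0.0448) and Ndufv2 -0.85 (adjusted p = 0.0464). The TCA cycle (-0.0087, adjusted p = 0.604) held falls of Dlat -1.36 (SE 0.218, adjusted p = 0.00246), Pcx -0.90 (adjusted p = 0.0231) and Dld -0.66 (adjusted p = 0.0251). Mitochondrial ribosomal proteins (-0.068, 4 called higher and 4 lower, adjusted p = 0.74) held Mrpl24 -2.20, Mrps31 -1.33 (SE 0.22, adjusted p = 0.003) and Mrps18b 1.29. In one-carbon and purine metabolism (-0.15, adjusted p = 0.066) Impdh2 -1.92 (SE 0.279, adjusted p = 0.00137, 43.7% of words shared) and Shmt2 -0.56 (SE 0.16, adjusted p = 0.0494) fell. Sdf2l1 fell (-1.19, SE 0.274, adjusted p = 0.0186) in the unfolded protein response (0.15, adjusted p = 0.785). Pprc1 fell (-0.79, SE 0.167, adjusted p = 0.0108), the coactivator list at 0.18 (adjusted p = 0.74). Among HCFC1 partners (0.061, adjusted p = 0.602) Zbtb17 rose (0.87, adjusted p = 0.0431) beside the fall of E2f1. Nqo1 rose (1.26, SE 0.276, adjusted p = 0.014), the NRF2 list at 0.20 (adjusted p = 0.284). Complexes II to IV (-0.037, adjusted p = 0.74), ATP synthase (0.16, adjusted p = 0.417) and fatty acid oxidation (0.00093, adjusted p = 0.787) stayed short of the threshold. So did the integrated stress response (-0.18, adjusted p = 0.528), p53 targets (0.037, adjusted p = 0.575) and the lysosome (0.20, adjusted p = 0.575).

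**Figure D2:**
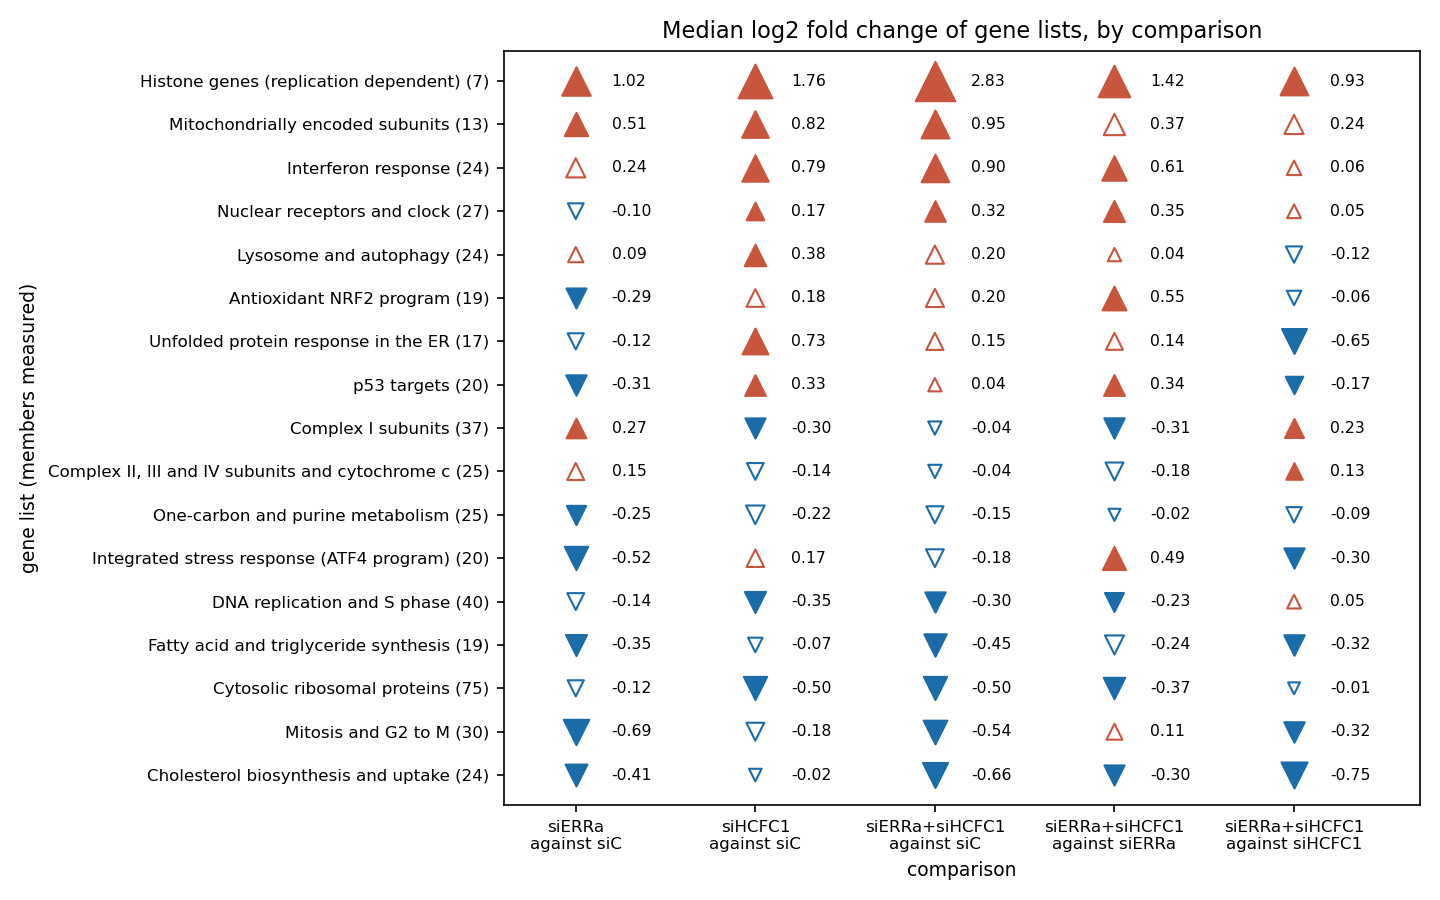
Median log2 fold change of 17 gene lists in the 5 comparisons. Filled triangles mark a camera adjusted p below 0.05 with an assumed correlation of 0.01, size follows the median, and numbers in brackets are members measured.

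**Figure D3:**
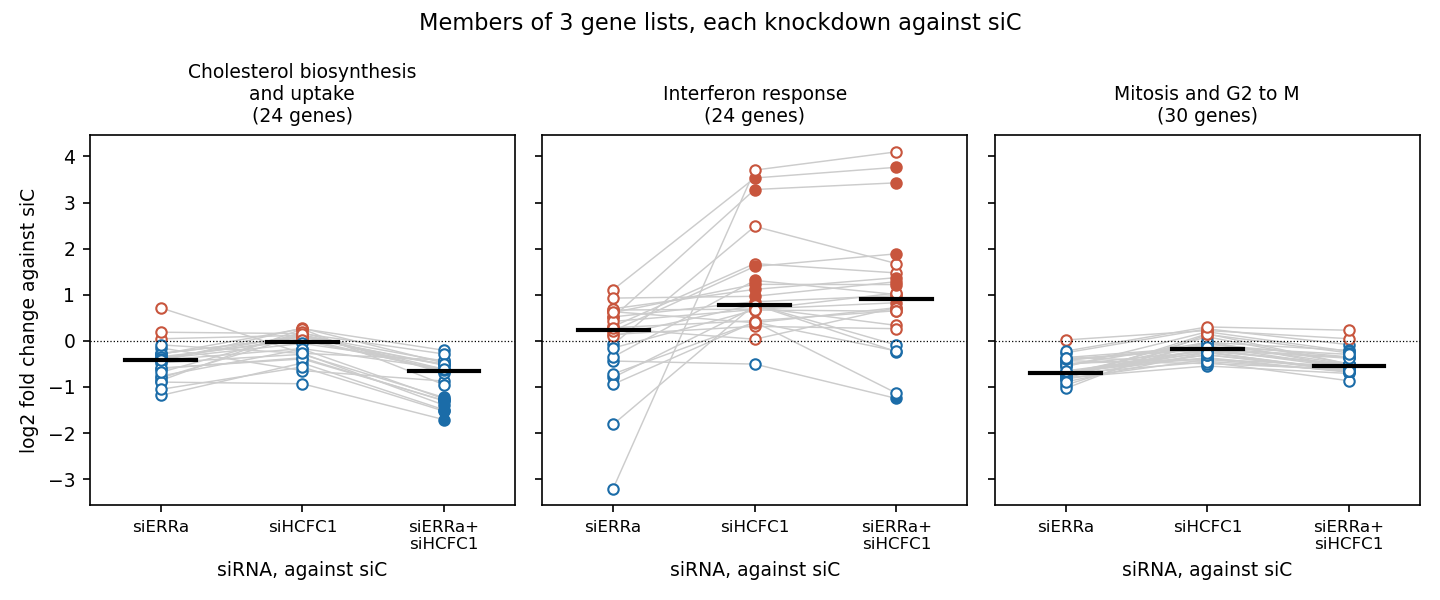
Log2 fold change of each measured member of 3 gene lists after each knockdown against siC. Filled points passed the threshold over all genes, black bars give the median, and grey lines join a gene.

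Adding siHCFC1 to siERRa changed many genes, while adding siERRa to siHCFC1 left 1 past the threshold in the main fit, a count that depends on the fit. Against siERRa, the matrix protein Tgfbi (chr 13, 56609523 to 56639562) rose from 1.74 ± 0.765 to 20.2 ± 6.22 TPM and Anxa8 from 2.30 ± 1.2 to 15.2 ± 4.68 TPM (SD, n = 3 each). Against siHCFC1, Fgfbp1 fell 3.73-fold, from 154 ± 36.6 to 42.4 ± 4.61 TPM (SD, n = 3 each). Its log2 change was -1.90 (SE 0.26, adjusted p = 0.0493), and it had also fallen after siERRa alone. Against siERRa the largest rise was that of the pseudogene Fabp3-ps1, at least 39.7-fold because siERRa held 0 counts (adjusted p = 0.0355). Ttc41 4.57 (SE 0.391), Tgfbi 3.68 (SE 0.446), the aldose reductase Akr1b7 3.14 (SE 0.466), Gpatch3 2.87 (SE 0.536) and Anxa8 2.80 (SE 0.381) followed, with an adjusted p of at most 0.0114. Fabp3-ps1 (chr 10, 86731987 to 86732388) lies inside Ttc41 on the other strand and shares 75% of its words with other genes, and Akr1b7 shares 27.7%. The largest falls were Neil1 -4.18 (SE 0.898), Mettl26 -3.56 (SE 0.336) and Lmnb2 -3.40 (SE 0.556). Rbbp9 -3.10 (SE 0.754), Fam234b -2.91 (SE 0.452) and Mfsd13a -2.91 (SE 0.367) came next, all 6 with an adjusted p of at most 0.0393. Without siERRa library 3 Gpatch3 was at 3.69. Leaving out library 1 of the combined knockdown moved Rbbp9 to -5.63, leaving out library 2 moved Neil1 to -5.69 and Lmnb2 to -4.06, and leaving out library 3 moved Neil1 to -3.56. The call of Neil1 ended without siERRa library 2 or 3 or library 1 of the combined knockdown, and that of Rbbp9 without any 1 of the siERRa libraries or library 2 or 3 of the combined knockdown.

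The combined knockdown differed from siERRa in 518 of 15965 genes, 225 higher and 293 lower (edgeR), and with the TPM as deposited (limma) in 100 higher and 239 lower. Leaving out siERRa library 1, 2 or 3 left 215, 324 or 281, and leaving out library 1, 2 or 3 of the combined knockdown left 300, 256 or 169. Of 37 named genes 16 kept their call in all 6 leave-one-out fits, and Fabp3-ps1, Aen, E2f1, Ncoa3 and Pcx lost it in all 6. The combined knockdown differed from siHCFC1 in 1 gene lower and 0 higher (edgeR), with 1159 genes at unadjusted p below 0.05 and 98 called by DESeq2. With a block for the library number 562 were called, so a count of 1 does not show that siERRa adds little. The edgeR count without the block was 0 without siHCFC1 library 2 or any 1 of the combined libraries and 2 without siHCFC1 library 3. The call of Fgfbp1 ended without siHCFC1 library 1 as well, with 1 other gene called. The authors' deposited comparisons call 716 (334 higher, 382 lower) against siERRa, with 472 of the 518 among them. Against siHCFC1 they call 35 (11 higher, 24 lower), Fgfbp1 among them.

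Relative to siHCFC1, the combined knockdown was lower in all 24 cholesterol genes (median -0.75, camera adjusted p = 4.91e-21, adjusted p = 0.0275 with an estimated correlation). It was lower in all 17 genes of the unfolded protein response (-0.65, adjusted p = 1.02e-16, adjusted p = 0.482 with an estimated correlation). So it was in all 30 mitosis genes (-0.32, adjusted p = 8.51e-08, adjusted p = 0.549 with an estimated correlation). These lists had 0 members called over all genes and 13, 8 and 1 adjusted over the list alone. The integrated stress response (-0.30, adjusted p = 0.000276), fatty acid synthesis (-0.32, adjusted p = 0.000331) and p53 targets (-0.17, adjusted p = 0.00329) were lower too. They had 0 members called, 2, 1 and 1 adjusted over the list alone, and adjusted p = 0.549, 0.533 and 0.549 with an estimated correlation. Complex I (0.23, adjusted p = 0.000581), histones (0.93, adjusted p = 0.00433) and complexes II to IV (0.13, adjusted p = 0.0488) were higher. These had 0 members called or adjusted over the list alone, and adjusted p = 0.763, 0.549 and 0.925 with an estimated correlation. Interferon (0.062, adjusted p = 0.523), ribosomal proteins (-0.013, adjusted p = 0.871) and S phase (0.047, adjusted p = 0.889) did not differ past the threshold. List calls ended without siHCFC1 library 3 for the integrated stress response (-0.17) and p53 (-0.028). Without siHCFC1 library 2 those of complex I (0.10), histones (0.36) and complexes II to IV (0.0079) ended, and without siHCFC1 library 1 the last (0.083). Without library 1 of the combined knockdown those of p53 (-0.16), histones (0.56) and complexes II to IV (0.041) ended, without library 2 that of p53 (-0.11) and without library 3 that of complexes II to IV (0.11).

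Some medians against siHCFC1 moved by more than 1.5 times while the call held. Without siHCFC1 library 1 mitosis was at -0.15 and the integrated stress response at -0.46. Without siHCFC1 library 2 cholesterol was at -0.50, mitosis at -0.49, fatty acid synthesis at -0.18 and p53 targets at -0.30. Without siHCFC1 library 3 complexes II to IV were at 0.29. Without library 1 of the combined knockdown the integrated stress response was at -0.16 and complex I at 0.12. Without its library 2 mitosis was at -0.17, the integrated stress response at -0.48 and complexes II to IV at 0.21, and without its library 3 the integrated stress response was at -0.51 and p53 targets at -0.31.

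Relative to siERRa, the combined knockdown was higher in interferon-response genes (median 0.61, camera adjusted p = 1.56e-06, adjusted p = 0.0741 with an estimated correlation). Of them 4 were called, and adjusted over the list alone 9 were higher and 1 lower. They included Gbp2 2.66 (SE 0.458, adjusted p = 0.00675), Gbp3 2.92 (SE 0.603, adjusted p = 0.0184) and Irf7 1.35 (SE 0.318, adjusted p = 0.0335). Over 22 settings Gbp3 ran from 1.08 to 3.08, with the call lost in 5. The NRF2 program was higher (0.55, adjusted p = 1.84e-05, adjusted p = 0.652 with an estimated correlation), with 3 called and 3 adjusted over the list alone. These were Nqo1 1.95 (SE 0.282, adjusted p = 0.002), Gclc 0.84 (SE 0.187, adjusted p = 0.026) and Gstm1 1.14 (adjusted p = 0.0387, 28.8% of words shared). Targets of p53 were higher (0.34, adjusted p = 0.00011, adjusted p = 0.53 with an estimated correlation), with 3 called and 6 adjusted over the list alone. The called ones were Gdf15 1.48 (SE 0.303, adjusted p = 0.0171), Bbc3 1.21 (SE 0.296, adjusted p = 0.0394) and Aen 0.73 (SE 0.188, adjusted p = 0.0496). The clock list (0.35, adjusted p = 0.000313), histones (1.42, adjusted p = 0.000998) and the integrated stress response (0.49, adjusted p = 0.00194) were higher. They had 5, 2 and 1 members adjusted over the list alone, and adjusted p = 0.0741, 0.53 and 0.652 with an estimated correlation. Over all genes 1, 0 and 1 were called, Nfil3 (1.23, SE 0.292, adjusted p = 0.0356) and Gdf15. Without siERRa library 2 the medians of NRF2 and the integrated stress response were 0.36 and 0.30, and without library 3 of the combined knockdown both were 0.32. Without siERRa library 3 that of p53 targets was 0.51.

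Lower than in siERRa were cytosolic ribosomal proteins (-0.37, adjusted p = 1.56e-06, adjusted p = 0.751 with an estimated correlation), with 0 called or adjusted over the list alone. Complex I was lower (-0.31, adjusted p = 7.12e-05, adjusted p = 0.652 with an estimated correlation), with 3 called and 9 adjusted over the list alone. The called ones were Ndufa3 -2.36 (SE 0.32, adjusted p = 0.00128), Ndufv2 -1.06 (adjusted p = 0.0288) and Ndufs7 -1.11 (SE 0.265, adjusted p = 0.0357). Cholesterol biosynthesis was lower (-0.30, adjusted p = 0.000998, adjusted p = 0.53 with an estimated correlation), with 2 called and 4 adjusted over the list alone. These were Hsd17b7 -1.13 (SE 0.257, adjusted p = 0.0276) and Lss -0.75 (SE 0.177, adjusted p = 0.0334). S-phase genes were lower (-0.23, adjusted p = 0.0323, adjusted p = 0.652 with an estimated correlation), with 2 called, Prim1 -1.47 (adjusted p = 0.0255) and E2f1 -0.69 (adjusted p = 0.0412). Adjusted over the list alone 3 were lower and 1 higher. Mitosis (0.11, adjusted p = 0.128), the unfolded protein response (0.14, adjusted p = 0.2) and the mitochondrially encoded subunits (0.37, adjusted p = 0.415) stayed short of the threshold. Other called members were Dlat -1.09 (adjusted p = 0.0145), Pcx -0.92 (adjusted p = 0.034), Mrps31 -1.05 (adjusted p = 0.0196), Mrpl24 -2.31 and Mrps18b 1.04. Impdh2 fell (-1.45, adjusted p = 0.0121) and the ERR coactivator Ncoa3 rose (0.79, adjusted p = 0.0444). Calls ended without siERRa library 3 for ribosomal proteins (-0.11), complex I (-0.12) and S phase (-0.15). That of S phase also ended without siERRa library 1 (-0.16) and without library 1 (-0.20) or 2 (-0.13) of the combined knockdown. The median of the ribosomal proteins was -0.60 without siERRa library 2 and -0.57 without library 1 of the combined knockdown.

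In the main fit the calls of the 2 single knockdowns shared few genes by number, a count that depends on the fit. The combined knockdown held 18 of 22 rises and 24 of 48 falls of siERRa. Of siHCFC1 it held 255 of 393 rises and 380 of 673 falls, so its larger number shared goes with the longer list. Of the calls against siC, siERRa and siHCFC1 shared 5 higher and 6 lower (independent lists would share 0.542 and 2.02), siERRa and the combined knockdown 18 and 24 (0.623 and 1.95), and siHCFC1 and the combined knockdown 255 and 380 (11.1 and 27.3). The 5 shared rises were Atp1b1, Frk, Nrep, Sntb1 and Trim12c, the 6 shared falls Dpp9, Fgfrl1, Mybl2, Nup210, Pbx4 and Pik3cd, and Rassf5 was lower in siERRa and higher in siHCFC1, names taken after their values were seen. All comparisons use the same siC libraries, which alone makes log2 changes correlate. Against 20 simulated data sets with no effect, the correlation across genes was 0.301 for siERRa with siHCFC1 (simulated mean 0.503), 0.496 for siERRa with the combined knockdown (0.505) and 0.627 for siHCFC1 with the combined knockdown (0.50), with covariances of 0.309, 0.484 and 0.806 (simulated 0.368, 0.370 and 0.367). The correlation of siERRa with siHCFC1 lay below the simulated range (0.486 to 0.518) and showed no excess. That of siERRa with the combined knockdown lay within its range (0.473 to 0.535), with a covariance above it (0.345 to 0.396). For siHCFC1 with the combined knockdown both lay above. Part of such an excess may still come from the shared controls. The simulation left out variation shared by a library number, so its values may be a poor baseline. Shared calls between siERRa and siHCFC1 numbered 11 and ran from 1 to 12 over the 9 leave-one-out fits of these groups. With a block for the library number, siHCFC1 shared 304 of 669 rises and 210 of 956 falls of siERRa. Independent lists would share 78.4 and 126. Another 38 of the 669 were called lower in siHCFC1, and 128 of the 956 higher.

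The effect of the combined knockdown departed from the sum of the single ones in 0 genes (edgeR, smallest adjusted p = 0.42), with 439 at unadjusted p below 0.05 and 5 called by DESeq2. Without a filter 14 were called, with a block for the library number 23, and with library weights (limma) 559. On simulated data this test recovered 31 of 66 genes with a 4-fold departure, 2 of 67 with a 2-fold one and 0 of 67 with a 1.5-fold one. Genes changed in the same direction by the combined knockdown against siC and against both single knockdowns numbered 0, a count that the 1 call against siHCFC1 held to at most 1. With the block there were 23 higher and 46 lower. Among lists, the unfolded protein response lay below the sum (median departure -0.54, 17 of 17 below 0, camera adjusted p = 1.9e-08, adjusted p = 0.889 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone, and the call held in all leave-one-out fits, at -0.32 without siHCFC1 library 2. Against siC the list differed by -0.12 after siERRa, 0.73 after siHCFC1 and 0.15 after both. The test over all 3 comparisons with siC found 1663 genes that differed in any group, and 993, 1044 and 1101 without siC library 1, siC library 3 and siERRa library 1.

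Lists of cell type markers stayed short of the threshold in all 5 comparisons. Medians ran from -0.18 to 0.25 for 5 measured mesenchymal markers (lowest adjusted p = 0.579) and from -0.34 to 0.93 for 5 macrophage and blood cell markers (0.214). They ran from -0.055 to 0.53 for 6 endothelial markers (0.42) and from -0.081 to 0.29 for 9 biliary markers (0.277). For 19 hepatocyte genes they ran from 0.062 to 0.32 (0.588). The highest of these, in siERRa against siC, was 0.18 without Ttr, which has 0 counts in siC. Single markers changed after siHCFC1. Csf1r (2.95, SE 0.69, adjusted p = 0.0205), Krt7 (0.91, SE 0.217, adjusted p = 0.0223) and Apob (1.43, SE 0.387, adjusted p = 0.041) rose. Col6a3 (-2.55, SE 0.526, adjusted p = 0.0109) and Des (-1.25, SE 0.341, adjusted p = 0.0425) fell. Col6a3 missed the filter of the limma settings, a TPM of at least 1 in at least 3 libraries, so its change lies near the floor. After the combined knockdown Csf1r (2.38, SE 0.678, adjusted p = 0.049) and Krt7 (1.14, SE 0.218, adjusted p = 0.00665) rose. Cd68 (-1.05, SE 0.271, adjusted p = 0.0321) and the hepatocyte regulator Hnf4a (-1.17, SE 0.263, adjusted p = 0.0165) fell. Csf1r was also higher than in siERRa (4.50, SE 0.771, adjusted p = 0.00654). Over 22 settings that change of Csf1r ran from 1.09 to 4.78. Its call in the combined knockdown against siC was lost in 15 of 22.

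Glycolysis, gluconeogenesis, hypoxia, cytokine and apoptosis lists stayed short of the threshold in all 5 comparisons. Medians ran from -0.28 to 0.14 for glycolysis (lowest adjusted p = 0.219), from -0.52 to 0.14 for gluconeogenesis and glycogen (0.14), from -0.30 to 0.26 for hypoxia targets (0.0698), from -0.28 to 0.21 for cytokine genes (0.0898) and from -0.0087 to 0.21 for apoptosis regulators (0.108). Interferon-response genes after siERRa (0.24, adjusted p = 0.381) did as well, with a median of 0.27 when Ifi44, which has 0 counts there, is left out. Called members were Pfkfb3 1.02 (SE 0.214, adjusted p = 0.0116) and Ppp1r3b -1.24 (SE 0.263, adjusted p = 0.0124) and the apoptosis gene Bmf -1.52 (SE 0.405, adjusted p = 0.0383) after siHCFC1. After the combined knockdown they were Pfkfb3 1.01 (adjusted p = 0.011), Ppp1r3c 0.99 (SE 0.169, adjusted p = 0.00345), the receptor Tnfrsf1b 1.11 (SE 0.265, adjusted p = 0.0222) and the proapoptotic Bcl2l11 0.86 (SE 0.17, adjusted p = 0.00789).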

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

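Of the tests below, those of RNA classes, of random matched lists and of splits of the libraries were set before their values were seen, and all others after the result they concern.

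Gene lists whose combined change departs from the sum of the single ones are the values this part starts from. By camera with an assumed correlation of 0.01 there were 7: the unfolded protein response (median departure -0.54, adjusted p = 1.9e-08), mitosis (0.301, adjusted p = 0.00053), cholesterol biosynthesis (-0.317, adjusted p = 0.00417), the NRF2 program (0.208, adjusted p = 0.0265), one-carbon metabolism (0.206, adjusted p = 0.0265), lysosome and autophagy (-0.209, adjusted p = 0.0413) and S phase (0.163, adjusted p = 0.0442). In each, 0 members were called, and adjusted p = 0.889 to 0.949 with an estimated correlation. The call of the unfolded protein response ended in no leave-one-out fit, with a median of -0.32 without siHCFC1 library 2. That of cholesterol ended without siHCFC1 library 2 (-0.093), with medians of -0.15 without siERRa library 2 and -0.21 without library 3 of the combined knockdown. That of mitosis ended without siHCFC1 library 2 (0.15) or library 3 of the combined knockdown (0.21), and its median was 0.15 without library 1 of the combined knockdown. That of NRF2 ended without siC library 3 (0.10), siERRa library 2 (0.10), siHCFC1 library 1 (0.22) or 2 (0.089) or combined library 3 (0.13), and its median was 0.33, 0.39 and 0.40 without siC library 2, siERRa library 3 and siHCFC1 library 3. That of one-carbon metabolism ended without siC library 1 (0.18) or 3 (0.19), siERRa library 2 (0.17), siHCFC1 library 1 (0.16) or 2 (0.20) or combined library 3 (0.14), and its median was 0.32 without siERRa library 3. That of the lysosome ended without siC library 3 (-0.22), siERRa library 2 (-0.16) or 3 (-0.26), siHCFC1 library 2 (-0.11) or 3 (-0.27) or combined library 1 (-0.18) or 3 (-0.22). Its median was -0.35, -0.32, -0.36 and -0.47 without siC library 2, siERRa library 1, siHCFC1 library 1 and combined library 2. That of S phase ended without siC library 1 (0.15) or 3 (0.17), siERRa library 2 (0.083), siHCFC1 library 2 (0.094) or combined library 1 (0.16) or 3 (0.14), and its median was 0.27 without combined library 2. The combined knockdown may hold less of each siRNA, which the labels do not state. Whether a weaker loss of Hcfc1 (96.2 CPM after siHCFC1, 113 after both) could explain a departure such as that of the unfolded protein response is left open, since cytosolic ribosomal proteins had medians of -0.503 after siHCFC1 (adjusted p = 0.788 with an estimated correlation) and -0.504 after both (adjusted p = 0.952 with an estimated correlation).

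By camera with an assumed correlation of 0.01 histone genes were higher after the combined knockdown (2.83, adjusted p = 0.0856 with an estimated correlation), and 3 explanations were tested. More RNA without poly(A) tails would raise other such RNAs: 42 genes of 4 RNA classes (snRNA, misc_RNA, rRNA and ribozyme) had a median of 0.551 (95% bootstrap interval 0.101 to 0.807, 0 called), but 29 of them average under 20 counts, so this stays undecided. A larger share of cells in S phase would raise replication genes, and these were lower (-0.305, adjusted p = 0.48 with an estimated correlation). They were lower after siHCFC1 as well, so the knockdown itself may lower them whatever the share of cells in S phase. This stays undecided too. Counted reads moving between near-identical tested histone genes would leave their sum unchanged. The sum over 21 tested histone cluster genes rose from 82.9 ± 18.9 CPM in siC to 326 ± 90.4 (SD, n = 3 each, ranges 67.4 to 104 and 238 to 418). This log2 ratio of 1.97 argues against such moves. Reads left out because they match several genes, or counted in untested histone genes, would not be in this sum. That part stays undecided. The sum was 133 ± 50.4 CPM after siERRa and 248 ± 109 after siHCFC1.

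Interferon-response genes were higher after siHCFC1, and 3 explanations were tested. A response to any transfected siRNA would also appear after siERRa, but the median difference of siHCFC1 from siERRa was 0.751 (21 of 24 members higher, camera adjusted p = 5.17e-06, adjusted p = 0.139 with an estimated correlation), which argues against it where the assumed correlation holds. Low expression of the members is argued against by random lists matched on expression: 0 of 10000, or 0%, reached the observed 0.785 (highest 0.566). Sequences of the siHCFC1 pool acting apart from Hcfc1 stay open: the list was higher in both groups that received the pool (0.902 after the combined knockdown, adjusted p = 0.0856 with an estimated correlation), and the 2 groups did not differ (adjusted p = 0.523). A separate siRNA against Hcfc1 would decide between them.

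Gapdh, often used as a reference gene, varied several fold between libraries: 62.3, 115 and 82.5 CPM in siC, 657, 568 and 1350 in siERRa, 848, 137 and 932 in siHCFC1 and 1090, 172 and 70.1 in the combined knockdown, in the order of the library numbers. It passed the threshold in no comparison (siERRa against siC log2 3.31, SE 0.858, adjusted p = 0.126). Counted reads moving between Gapdh and its 66 tested copies are argued against, since their sum still differed by a log2 ratio of 1.92. Reads left out because they match several genes would be in no sum. Whether such reads were counted is not stated, so that part stays undecided. Swapped labels between siHCFC1 and siERRa are argued against by Esrra, with a lowest value of 46.4 CPM in siHCFC1 and a highest of 16.9 in siERRa; this says nothing about the combined library with high Gapdh. A rise of glycolysis as a whole is argued against by the other 19 members, with a median of 0.0482 (95% bootstrap interval -0.0214 to 0.0939, 0 called). The cause is open, and the deposited counts of Gapdh could not serve as a reference in these samples.

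Whether counts of changed genes exceed those of regrouped libraries was tested on splits. The 5 pairwise comparisons allow 10 splits each, too few for a share under 5%. The real grouping was the only one to reach 70 (siERRa against siC, 1 of 10, highest other 0), 1066 (siHCFC1 against siC, 1 of 10, highest other 0), 1100 (combined against siC, 1 of 10, highest other 0) and 518 genes (combined against siERRa, 1 of 10, highest other 0). Combined against siHCFC1 reached its 1 gene in 2 of 10 (highest other 1). The count over any group was reached by 1 of 100 splits (highest other 217 against 1663), which argues against a random grouping as its source. The overlap of siERRa with siHCFC1 was reached by 1 of 100 (highest other 10 against 11). Its splits mix the siC, siERRa and siHCFC1 libraries, so they ask whether any group differs. They cannot tell whether the knockdowns share more genes than unrelated effects would. For the departure from additivity this test is void, since the real count is 0 and 100 of 100 splits must reach it. Another split called 903 genes there. A regrouping can carry the effect of a knockdown into this contrast, so that count may come from the groups themselves.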

How the results depend on the processing

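The settings below were fixed before the data were seen, except the fits without libraries numbered 2 or 3 and those of the compared libraries only, which were added afterwards. Counts are given in the order siERRa against siC, siHCFC1 against siC, combined against siC, combined against siERRa, combined against siHCFC1, where a setting moved them by more than 1.5 times. The main counts are 70, 1066, 1100, 518 and 1, with 1663 in any group, 11 shared by siERRa and siHCFC1, and 0 departures. Among targets, named genes and lists, no setting called a result in the other direction.

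At an adjusted p of 0.01 the counts were 9, 314, 382, 115 and 0, with 628 in any group and 1 shared. With limma on log2(TPM + 0.5) siERRa gave 24, combined against siERRa 339 and against siHCFC1 3, with 5 shared and Hcfc1 at -1.03 in siHCFC1 (past the threshold), and the median shift per gene was -0.158 and -0.134 in siHCFC1 and the combined knockdown. With a pseudocount of 0.1 these were 21, 302, 0, 3 shared and -1.03, and with 2 they were 32 for siERRa, 3 against siHCFC1, 7 shared and -0.99. Library weights gave 1523, 5202, 5922, 3835 and 2619, with 559 departures, 8204 in any group, 593 shared, and Hcfc1 at -1.01 and -0.69. Without a filter siERRa gave 313, combined against siERRa 940, against siHCFC1 82, with 14 departures, 2779 in any group, 80 shared and Hcfc1 at -0.84. With TPM of at least 5, and with RLE scaling, combined against siHCFC1 gave 0. DESeq2 gave 395, 1865, 1899, 1181 and 98, with 5 departures, 3139 in any group, 98 shared and Hcfc1 at -0.79. Quantile normalization, the robust fit, the fit without mitochondrially encoded genes and a fold of at least 1.5 moved no count by that much. With quantile normalization the 1 call against siHCFC1 was higher in place of lower, another gene than Fgfbp1.

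With a block for the library number the counts were 1625, 3974, 4067, 3191 and 562, with 23 departures, 6114 in any group, 514 shared, and Hcfc1 past the threshold at -0.90 in siHCFC1 and -0.66 in the combined knockdown. Changed in the same direction by the combined knockdown against siC and against both single knockdowns were 23 genes higher and 46 lower with the block, and 0 without it. The block was not used because the labels do not say that the numbers pair the samples and the values fell short of the threshold set for it. They do show variation shared by libraries of a number. After group means are taken out, 18 same-number pairs correlated from 0.033 to 0.37 (median 0.26), 36 other cross-group pairs from -0.33 to 0.070, and 11 of 12 libraries were closest to one of their own number. The lowest pair in the 5 comparisons (0.0958, 0.0590, 0.0326, 0.0949 and 0.0650) lay below 0.1, a threshold fixed beforehand and not taken from the calls, though the blocked calls had been seen before this check. All same-number pairs below 0.1 were of libraries numbered 1, and those numbered 2 or 3 ran from 0.208 to 0.373. The threshold was thus missed only through number 1, and the main fit counts differences between the numbers as spread. A call that comes or goes with the block is not a stronger or weaker effect.

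Without the libraries numbered 2 combined against siHCFC1 gave 0, and Hcfc1 was at -1.21 in siHCFC1. Without those numbered 3 the counts were 1, 259, 269, 62 and 0, with 342 in any group, 0 shared, and Esrra at -1.79 and -1.16, both short of the threshold. With only the compared libraries siERRa gave 26, combined against siERRa 243 and against siHCFC1 0, with 4 shared. Leaving out 1 library gave 8 to 24 for siERRa, 420 to 745 for siHCFC1 (420 to 643 where moved), 476 to 684 for the combined knockdown, 169 to 324 against siERRa, 0 to 2 against siHCFC1, 993 to 1585 in any group (993 to 1101 where moved), 1 to 12 shared (1 to 7 where moved) and 0 departures throughout. Hcfc1 in siHCFC1 ran from -1.07 to -0.62 and passed the threshold at -1.07, without siHCFC1 library 2. Named genes lost their call in 414 of 1026 leave-one-out fits.

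Of 55 list calls, estimating the correlation kept 2, interferon in siHCFC1 (adjusted p = 0.0374) and cholesterol in the combined knockdown against siHCFC1 (adjusted p = 0.0275). The fits without numbers 2 and 3 each lost 7, quantile normalization 5, TPM with 0.5 or 0.1, library weights and RLE 2 each, TPM with 2 lost 1 and the block 0. Leaving out 1 library lost 61 of 372. The lysosome list after siHCFC1 was lost with TPM + 0.5 (0.18), library weights (0.075) and quantile normalization (0.24). The promoter motif test and its alternatives were not run.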

Other observations

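The genes of this part were chosen after their values were seen. The libraries numbered 3 of all 4 groups held more RNA of immediate-early genes than the other 8: Fos 132 to 359 CPM against 4.48 to 19.0, Fosb 282 to 795 against 3.67 to 12.3, Egr1 945 to 1470 against 75.0 to 168, Jun 124 to 205 against 13.2 to 45.7, Atf3 56.1 to 113 against 7.99 to 25.4, Dusp1 307 to 356 against 33.4 to 142 and Ier2 129 to 186 against 46.6 to 78.3. The mitochondrially encoded share of counts also followed the number, 5.81% for number 1 (4.56 to 6.72), 10.4% for number 2 (6.54 to 14.5) and 3.02% for number 3 (2.37 to 3.59). The first 2 principal components held 23.1% and 18.9% of the variance.

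Hcfc2, the paralog of Hcfc1, held 49.5 ± 3.50 CPM in siC, 67.9 ± 5.48 in siERRa, 66.9 ± 9.75 in siHCFC1 and 75.0 ± 3.84 in the combined knockdown (SD, n = 3 each). Esrrg, a paralog of Esrra, held 0.0694 ± 0.12 CPM in siC, 0.422 ± 0.149 in siERRa, 0.176 ± 0.305 in siHCFC1 and 1.10 ± 0.354 in the combined knockdown (SD, n = 3 each), at most 1.51 in any library.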
